A study of Mus musculus with 12 samples.

How the data were processed

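Gene expression was measured in whole ear tissue of wild-type mice, labelled C57BL/6J, and of mice lacking both cannabinoid receptors (Cnr1 and Cnr2). The measurement used 12 one-colour Affymetrix Mouse430_2 arrays, 3 per group. Per the labels, females of 8 to 10 weeks were sensitized with 50 µl of 0.2% dinitrofluorobenzene (DNFB) on the shaved abdomen. On day 5 the right ear received 10 µl of 0.3% DNFB while the left ear stayed untreated, and both ears were taken 48 h later. Each array was hybridized with 10 µg of labelled cRNA made from 5 µg of total RNA.

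The deposited values are one linear intensity per probe set and array. Per the submitters' processing notes the authors made them with GCRMA, whose version and background settings are not given. The values are never negative and have array medians of 24.7 to 30.1, so they were read as linear, and log2 values were computed here with no pseudocount. The deposited instrument records of the arrays hold no expression values (unit: other). The washing run of each array was inferred from their hybridization times and fluidics modules, with a new run after a gap in time. They were used for nothing else. The number of arrays limits the precision of every value.

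The table holds 45101 probe sets. Of these, 64 are Affymetrix controls, 34958 carry one gene symbol, 932 carry several and 9211 carry none, and the Entrez identifier of 34754 single-symbol probe sets matched the annotation used here. A probe set was tested if its intensity was at least 16 in at least 3 of the 12 arrays, which left 29460. Below that intensity, fold changes depend on how GCRMA handles background. A gene's value is that of its tested single-symbol probe set with the highest mean over all arrays, which gave 13383 of the 18193 genes on the array. Counts are given per probe set or per gene as stated. Fold changes of genes with all 3 arrays of a group below 16 are given as "at least" the fold against 16, a rule added after seeing the data and also used where only the mean of the group was below 16; list medians are then also given at the bound, with values below 16 set to 16. Families of near-identical genes (Sprr2, Stfa, Lce, Krtap, Saa, Serpinb3) can share probes, so the member named is uncertain.

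A linear model with one coefficient per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), giving 5 comparisons: DNFB against control ears in each genotype, knockout against wild type in each kind of ear, and the difference of the responses. P-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Values are log2 fold changes ± SE of the model unless said otherwise. The 31 gene lists (555 genes, 13 of them in more than 1 list) were tested with camera at its preset correlation of 0.01, adjusted over the lists within a comparison. Camera asks whether a list moved more than the other genes. Each list was also tested with camera and an estimated correlation and with fry, which asks whether its genes moved one way (directional) or either way (mixed).

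The genes named in the text followed a rule. For each comparison they were drawn from the 10 genes with the highest and the 10 with the lowest log2 fold change. Not all of these are printed. Only genes past the threshold whose groups do not overlap were ranked, leaving out clone and locus names. With fewer than 5 such genes, the 5 with the smallest p are named instead. Up to 4 members of each list with the largest change are added, and Cnr1, Cnr2 and Ccl8 are named whatever their values. The groups, comparisons, lists, tests and naming rule, and all alternatives but those said to be added, were chosen before the data were examined.

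Per-mouse values of a list are means over its genes of DNFB-treated minus control ear, compared between 3 and 3 mice by a two-sided exact permutation test whose smallest p is 0.1. The ears of a mouse are paired by the labels, which name no paired test, so mouse was used only as an alternative block. The deviations of a mouse's arrays from their group means correlated between -0.00426 and 0.0797 across probe sets. Genotype calls among the 100 tested genes nearest to Cnr1 and to Cnr2 were compared with the other genes by a two-sided Fisher's exact test. The fit was tested on simulated data with 200 changed probe sets per comparison. It recovered 60% of the 2-fold and 92% of the 4-fold changes in the wild-type response, 61% and 90% in the knockout response, 47% and 91% in the genotype difference in DNFB-treated ears, 54% and 95% in that in control ears, and 29% and 75% in the difference of the responses. False calls were 2.5% to 8.09% of the calls. The simulation changed far fewer probe sets than passed in the real responses and used independent noise. Its rates are therefore not the power or the false call share of the real comparisons.

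The alternatives were no filter, a stricter filter at an intensity of 64, eBayes with trend and robust, another quantile normalization, centring each array on its median, adding 32 before the log2, array weights, only the groups compared, washing run as a fixed block, mouse as a block, the mean of a gene's probe sets, calls of at least 2-fold, and each array left out in turn. Added after seeing the data were the washing run as a random block, the normalization and run alternatives for the lists, and 10 further gene lists. No group has 4 to 10 arrays, so no single array was tested for standing apart. Probe sets without a symbol or with several stayed in the probe set counts and were left out of the gene values and lists. Random blocks used statmod 1.5.0; figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.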

Results

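The data are 12 arrays from 6 mice, 3 of each genotype, with 1 DNFB-treated and 1 untreated control ear per mouse. DNFB is a contact allergen, and a challenge of sensitized mice produces allergic contact dermatitis (contact hypersensitivity) in the painted ear. Between 57.7% and 61.5% of the probe sets of an array reached an intensity of 16. Across probe sets, the 12 pairs of arrays from one group correlated at r = 0.957 to 0.971, and the pairs from different groups at 0.868 to 0.966. The first principal component held 57.6% of the variance and the second 6.76%. By the runs inferred from the instrument records, the arrays were washed in 3 runs of 4. Run 1 held the 3 wild-type control ears and wild-type DNFB ear 1, run 2 held wild-type DNFB ears 2 and 3 with knockout control ears 1 and 2, and run 3 held knockout control ear 3 with the 3 knockout DNFB ears. With the run as a fixed block, the wild-type response thus rests on DNFB ear 1 and the knockout response on control ear 3. The difference of the responses then rests on both of these single arrays. As a sign of RNA quality, the log2 ratio of the 3' to the 5' control probe sets of Actb was 0.66 ± 0.07 (SD, n = 3) in wild-type control, 0.52 ± 0.08 in wild-type DNFB, 0.48 ± 0.02 in knockout control and 0.42 ± 0.01 in knockout DNFB ears. That of Gapdh was -0.40 ± 0.08, -0.35 ± 0.03, -0.38 ± 0.06 and -0.32 ± 0.06 in the same order.

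The first comparison asks what DNFB challenge changes in ears with intact cannabinoid receptors. In wild-type ears, Krt6b, a keratin of wounded and hyperproliferative epidermis, rose 256-fold (log2 8.00 ± 0.45, n = 3 per group), to a mean intensity of 7938, near the highest intensity on those arrays (8124 to 9243), where signals can saturate. Cxcl9, an interferon-induced chemokine that attracts T cells, rose at least 112-fold, to 1797. Saa3, an acute phase protein, rose at least 75.7-fold, the neutrophil-associated Stfa2l1 at least 76.6-fold, and Gzmb, a protease of cytotoxic granules, at least 23.3-fold. Acod1, which makes itaconate in activated macrophages, rose at least 21.8-fold, the neutrophil chemokine Cxcl5 at least 12.4-fold, the cornified envelope genes Sprr2f and Lce3a at least 56.9-fold and 25.8-fold, and Stfa3 168-fold. Among the genes with the deepest decreases, the keratin Krt24 fell 11.4-fold (log2 -3.51 ± 0.26), from 2370 to 208. Angptl7, a secreted angiopoietin-like protein, fell 8.31-fold and Slc6a2, the noradrenaline transporter, fell 7.8-fold. Vipr1, a receptor for vasoactive intestinal peptide, fell at least 1.2-fold, Mucl1 at least 3.15-fold and Lypd2 at least 4.3-fold (a call lost with washing run as a block), all toward intensities below 16.

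**Figure D1:**
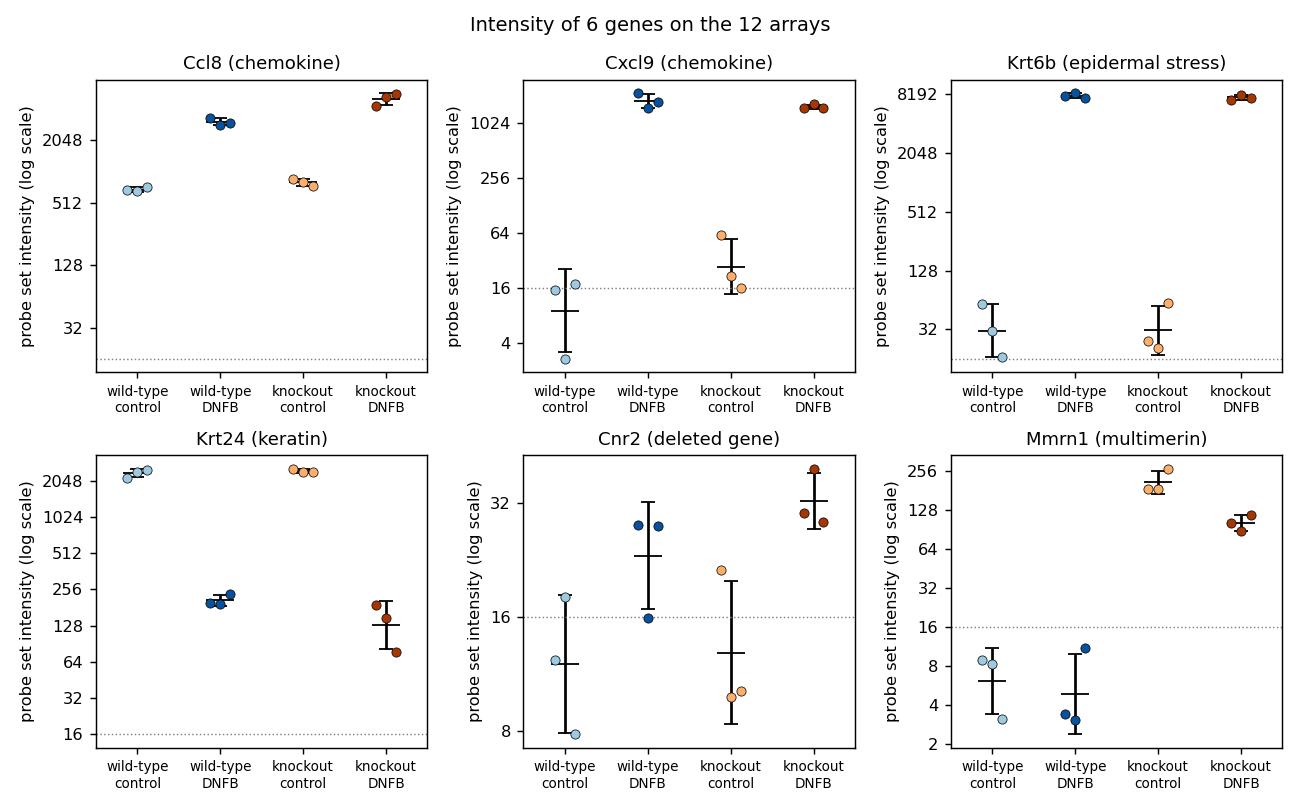
Probe set intensity (log axis) of Ccl8, Cxcl9, Krt6b, Krt24, Cnr2 and Mmrn1 on each of the 12 arrays; bars show the geometric mean and SD on the log2 scale (n = 3 per group), and the dotted line marks an intensity of 16. Krt6b reached 7938 in wild-type DNFB-treated ears, while Mmrn1 lay at 6.16 and 4.87 in wild-type and at 209.8 and 102.0 in knockout control and DNFB ears.

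Immune genes moved together in wild-type ears. Of 28 chemokines tested, 19 rose (20 adjusted over the list alone) and none fell, with a median log2 change of 1.87 (1.67 with genes below 16 at their bound); Cxcl2 rose at least 49.9-fold and Ccl3 at least 8.81-fold. The monocyte chemokine Ccl8 rose by 2.17 ± 0.12, from 685 to 3079. Of 19 inflammatory cytokines and receptors, 16 rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.64 (1.22 at the bound). Il1b, the main secreted interleukin 1, rose by 5.50 ± 0.31, Il6 rose at least 6.03-fold and Ifng, the T cell cytokine interferon gamma, at least 1.81-fold. All 23 interferon-induced genes rose, with a median of 2.98, among them the GTPases Gbp2 (4.93 ± 0.20) and Iigp1 (4.24 ± 0.30). All 11 genes of MHC class I presentation rose (median 1.54), led by the immunoproteasome subunits Psmb8 (3.30 ± 0.14) and Psmb9 (2.97 ± 0.12). These 4 lists were shifted by camera, with adjusted p = 6.8e-08, 3.0e-07, 1.3e-18 and 1.95e-11, and stayed so with an estimated correlation (adjusted p = 0.038, 0.039, 0.039 and 0.0235). All 10 genes of MHC class II presentation rose as well, with a median of 1.30 (1.20 at the bound); Cd40 rose by 1.83 ± 0.22 and the class II regulator Ciita at least 2.61-fold. The adjusted p of that list was 5.4e-07, and adjusted p = 0.060 with an estimated correlation. Of 11 complement genes, 10 rose (11 adjusted over the list alone), with a median of 1.03, C3ar1 by 2.20 ± 0.13 and Cfb by 2.04 ± 0.20 (adjusted p = 4.95e-07; adjusted p = 0.149 with an estimated correlation). Of 11 genes of alternative activation and type 2 immunity, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 1.13 (0.97 at the bound). The chitinase-like Chil3 rose at least 22.2-fold and the lipoxygenase Alox15 at least 3.31-fold (adjusted p = 0.0135; adjusted p = 0.064 with an estimated correlation).

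Markers of infiltrating leukocytes rose, and some of a resident type fell. Of 14 neutrophil markers, 12 rose and 1 fell, with a median of 3.61 (3.36 at the bound); the receptors Fpr2 and Clec4e rose at least 13.5-fold and 11.2-fold (adjusted p = 5.1e-06; adjusted p = 0.060 with an estimated correlation). Of 18 monocyte and macrophage markers, 17 rose and 1 fell, with a median of 1.87, among them Plac8 (4.31 ± 0.17) and the Fc receptors Fcgr1 (3.85 ± 0.18) and Fcgr4 (at least 26.5-fold) (adjusted p = 1.1e-12; adjusted p = 0.060 with an estimated correlation). Of 23 T and NK cell markers, 16 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 1.67 (0.82 at the bound); Gzma rose at least 24.8-fold and Cd8b1, part of the CD8 co-receptor, at least 4.83-fold. That list passed with adjusted p = 1.8e-07, and 0.0235 with an estimated correlation. The counts adjusted over the list alone equal those over all genes for the neutrophil and monocyte lists. Among 13 dendritic and Langerhans cell markers, 5 rose and 1 fell, the migration receptor Ccr7 rising at least 1.84-fold and Cd207, the langerin of epidermal Langerhans cells, falling by 2.68 on the log2 scale, from 167 to 26.1. In the 12 mast cell and basophil markers, 3 rose and 2 fell; the basophil protease Mcpt8 rose at least 6.32-fold and Hdc, which makes histamine, at least 15.3-fold. The median of that list was -0.10 (-0.06 at the bound) while its mean was 0.84 and camera pointed up. Of 5 B and plasma cell markers 2 rose, Ighm by 1.03 ± 0.16, with a median of 0.88 (0.17 at the bound), and of 3 eosinophil markers 2 rose, with a median of 2.15 (0.14 at the bound). Of 16 endothelial markers 5 rose and 1 fell, with the adhesion molecules Vcam1 (1.67 ± 0.25), Sele (1.40 ± 0.15) and Icam1 (1.26 ± 0.11) among those that rose. These last 5 lists, whose counts were the same adjusted over the list alone, did not pass as lists (adjusted p = 0.084, 0.612, 0.084, 0.067 and 0.062).

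The structural tissues of the ear moved in both directions. Of 21 genes of epidermal stress and hyperproliferation, 19 rose and none fell, with a median of 4.47 (4.10 at the bound). The list passed camera with adjusted p = 8.4e-14, and gave 0.060 with an estimated correlation. S100a9, an antimicrobial calcium-binding protein, rose by 6.81 ± 0.68. It is also in the neutrophil list, so its rise in whole ears cannot be assigned to the epidermis. Of 28 cell cycle genes, 27 rose, with a median of 1.88, among them the mitotic genes Cenpe (2.55 ± 0.19), Bub1 (2.53 ± 0.45) and Birc5 (2.33 ± 0.14); the list passed with adjusted p = 8.9e-18, and 0.045 with an estimated correlation. Of 22 genes of epidermal differentiation and barrier, 5 rose and 7 fell (7 and 8 adjusted over the list alone): Casp14, a protease of cornification, rose by 2.04 ± 0.19 and Krt1, a keratin of the spinous layer, by 1.35 ± 0.12, while the basal keratin Krt15 changed by -1.94 ± 0.20. The list's median was -0.12, its mean was 0.08 and camera pointed up (adjusted p = 0.949). Of 19 hair follicle genes, 11 rose (13 adjusted over the list alone), with a median of 3.56 (2.01 at the bound); the hair keratin Krt25 rose by 4.53 ± 0.92 and Krt34 at least 3.82-fold (adjusted p = 2.85e-04; adjusted p = 0.439 with an estimated correlation). Of 16 genes of sebaceous gland and lipid synthesis, 13 fell (15 adjusted over the list alone), with a median of -0.96, the desaturase Scd3 by -2.07 ± 0.31 and the lipogenic regulator Srebf1 by -1.27 ± 0.09 (adjusted p = 2.8e-05; adjusted p = 0.199 with an estimated correlation). Of 21 skeletal muscle markers 18 fell (19 adjusted over the list alone; median -0.88, Actn3 by -1.30 ± 0.25), and of 15 cartilage markers 11 fell (median -1.44, or -1.39 at the bound), Cnmd by -1.90 ± 0.20 and the proteoglycan Acan by -1.64 ± 0.20. Of 13 adipocyte markers 10 fell (median -0.76), Cidea by -1.72 ± 0.20 and the hormone Lep by -1.62 ± 0.30, and of 10 nerve and Schwann cell markers 6 fell and 1 rose (median -0.85), S100b by -2.05 ± 0.18 and the myelin protein Mbp by -1.79 ± 0.16. These 4 lists passed with adjusted p = 3.8e-05, 1.1e-05, 9.8e-04 and 0.0192, and gave adjusted p = 0.427, 0.136, 0.397 and 0.412 with an estimated correlation. For cartilage, adipocyte and nerve lists the counts adjusted over the list alone were the same.

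The remaining lists did not pass in wild-type ears. Of 20 genes of extracellular matrix and remodelling, 7 rose and 8 fell (8 and 8 adjusted over the list alone; median 0.02, adjusted p = 0.743), with the protease inhibitor Timp1 at 3.02 ± 0.25 and Adam8 at 2.64 ± 0.23. Of 18 genes of the endocannabinoid system, 5 rose and 6 fell (6 and 6 adjusted over the list alone; median -0.29, or -0.24 at the bound, mean 0.08, adjusted p = 0.893). Ptgs2, the inducible cyclooxygenase, rose at least 13.0-fold, and Mgll, which degrades the endocannabinoid 2-arachidonoylglycerol, fell by 1.53 on the log2 scale. Of 15 immediate early genes, 2 rose and 1 fell (1 and 0 adjusted over the list alone); the median was -0.14 while camera pointed up (adjusted p = 0.949). Of 12 fibroblast markers, 1 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of -0.41 and Dpt at -1.10 ± 0.16 (adjusted p = 0.112). Of 9 melanocyte markers 1 fell (0 adjusted over the list alone; median -0.44, adjusted p = 0.297). None of 3 erythroid markers passed (median -0.09, or -0.04 at the bound, adjusted p = 0.999), and of 4 bone and bone marrow markers 1 rose and 1 fell (median 0.45, or 0.24 at the bound, adjusted p = 0.934).

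Across the array, 4485 probe sets were higher and 6726 lower in wild-type DNFB than control ears. By gene, 2545 were higher and 3216 lower, 43.0% of the 13383 genes. Of the probe sets, 1720 and 1851 changed at least 2-fold. Of the 31 lists, camera shifted 13 up and 5 down, in the same direction in each of the 3 mice, and 6 calls remained with an estimated correlation. With washing run as a block, 5624 probe sets passed and the nerve and Schwann cell list did not (median -0.64 against -0.85, adjusted p = 0.076), while the eosinophil list did (adjusted p = 0.0281). The median log2 change of all probe sets was -0.137, and -0.022 with each array centred on its median, where 5602 probe sets were higher and 4968 lower; all 18 list calls remained. Leaving out 1 array added list calls: dendritic cells without control array 1 (adjusted p = 0.035), fibroblasts without control array 2 (0.045), eosinophils without control array 3 (0.0203), and endothelium without DNFB array 1 (0.049) or 2 (0.0241).

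**Figure D2:**
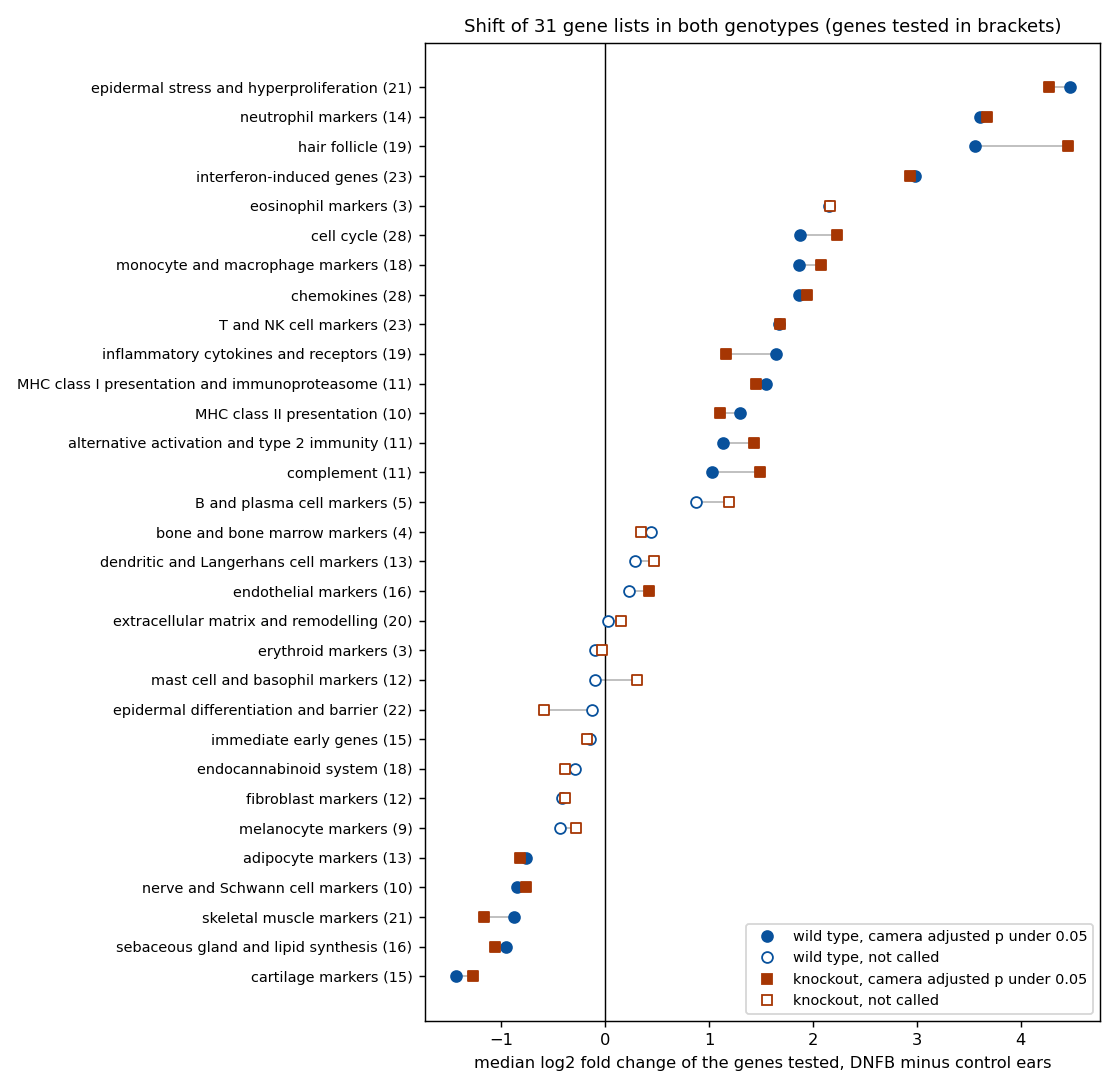
Median log2 fold change, DNFB minus control ears, of the tested genes of each of 31 gene lists in wild-type and knockout ears; filled points passed camera with an adjusted p under 0.05 and open points did not. The medians of the interferon-induced genes were 2.98 and 2.94, and those of the cartilage markers -1.44 and -1.27.

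The same comparison in knockout ears asks what DNFB changes without the receptors. Acod1 rose at least 31.8-fold and the neutrophil chemokine Cxcl2 at least 62.1-fold, Stfa2l1 at least 82.5-fold and Krt6b by 7.94 ± 0.45 (n = 3 per group), from 31.2 to 7639, near the highest intensity on those arrays (8039 to 9661), where signals can saturate. Saa3 rose at least 81.1-fold, Sprr2f at least 33.1-fold, Slfn1 at least 10.8-fold, the hair keratin-associated gene Krtap11-1 at least 10.1-fold and Has3, a hyaluronan synthase, at least 6.05-fold. Krt24 fell by 4.25 on the log2 scale, from 2468 to 129.6, and Angptl7 changed by -3.40 ± 0.16. The airway and skin secretory protein Scgb1a1 fell at least 3.64-fold, Mucl1 at least 2.56-fold (lost with washing run as a block) and Phf24 at least 2.1-fold.

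Of the chemokines, 21 rose and 1 fell, adjusted over the list alone as well (median 1.95, or 1.89 at the bound), Ccl8 by 2.67 ± 0.12 from 804 to 5117. Of the cytokines and receptors, 14 rose (15 adjusted over the list alone) and 1 fell (median 1.17, or 1.05 at the bound), with Il1b at least 71.2-fold higher. All 23 interferon-induced genes (median 2.94), all 11 class I genes (median 1.45), all 10 class II genes (median 1.10) and all 11 complement genes (median 1.49) rose, among them Ifit1 (at least 18.7-fold), Psmb8 (3.09 ± 0.14), Cd40 (2.03 ± 0.22) and C3ar1 (2.62 ± 0.13). Of the type 2 genes 8 rose and none fell (8 and 1 adjusted over the list alone; median 1.43), with Arg1, an arginase of alternatively activated macrophages, at 3.56 ± 0.39, reaching 601. Neutrophil markers (11 of 14 rose, 12 adjusted over the list alone, 1 fell; median 3.67, or 3.45 at the bound), monocyte and macrophage markers (17 of 18; median 2.08) and T and NK cell markers (15 of 23, 1 fell; median 1.68, or 1.36 at the bound) rose too, and 7 of 16 endothelial markers (8 adjusted over the list alone) rose (median 0.42). Cd207 changed by -2.73 ± 0.34. With an estimated correlation, chemokines, interferon-induced genes, class I, type 2, cell cycle and T and NK lists kept their calls (adjusted p = 0.040, 0.041, 0.030, 0.041, 0.041 and 0.030). The values with an estimated correlation for cytokines, class II, complement, neutrophils, monocytes and endothelium were adjusted p = 0.057, 0.079, 0.144, 0.071, 0.070 and 0.337.

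Of the epidermal stress genes 19 of 21 rose and 1 fell (median 4.27, or 3.66 at the bound), Krt16 by 6.45 ± 0.48, and of the cell cycle genes 27 of 28 rose (median 2.23), Bub1 at least 11.3-fold. Of the 22 epidermal differentiation genes, 6 rose and 12 fell (6 and 13 adjusted over the list alone), with a median of -0.59, the barrier lipoxygenases Aloxe3 at -1.62 ± 0.11 and Alox12b at -1.47 ± 0.18; the list did not pass (adjusted p = 0.099). Hair follicle genes (16 of 19; median 4.46, or 2.76 at the bound) rose, Krt25 at least 62.6-fold. All 16 sebaceous and lipid genes (median -1.06), 19 of 21 muscle (21 adjusted over the list alone; median -1.17), 13 of 15 cartilage (median -1.27, or -1.15 at the bound), 9 of 13 adipocyte (11 adjusted over the list alone; median -0.82) and 5 of 10 nerve markers (median -0.76, 1 rose) fell. Examples are Dgat2, which makes triglycerides (-1.57 ± 0.12), the muscle actin-binding Actn3 (-1.89 ± 0.25), Col9a1 (-1.73 ± 0.23), Cidea (-2.19 ± 0.20) and S100b (-2.06 ± 0.18). With an estimated correlation, the epidermal stress, hair follicle, sebaceous, muscle, cartilage, adipocyte and nerve lists gave adjusted p = 0.101, 0.322, 0.125, 0.322, 0.144, 0.322 and 0.402.

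In knockout ears 5020 probe sets were higher and 6481 lower, and 1977 and 1963 of them changed at least 2-fold. By gene, 2837 were higher and 3286 lower, 45.8% of the 13383 genes. Camera shifted 14 lists up and 5 down, in the same direction in each of the 3 mice; with an estimated correlation 6 of these 19 calls remained. With washing run as a block, 5791 probe sets passed and the endothelial list did not, at a similar median (0.38 against 0.42, adjusted p = 0.0565). With this block the epidermal differentiation list passed downward (adjusted p = 0.034) and the eosinophil list upward (adjusted p = 0.0243). Without knockout control array 2 the nerve and Schwann cell list was lost (adjusted p = 0.0543), and without knockout DNFB array 3 the endothelial list was (adjusted p = 0.055). In the endocannabinoid list, which did not pass, the median was -0.39 and the mean 0.10.

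The responses of both genotypes were then set side by side. Across 13383 genes the log2 changes correlated at Pearson r = 0.906 and Spearman rho = 0.862. The slope of knockout against wild type was 1.07 by total least squares, which treats both axes alike and is not a regression slope. Genes are not independent replicates, so no p is given. Of the genes called higher, 2191 were shared, against 539.5 if the calls were independent. Of those called lower, 2528 were shared against 789.64, and 1 gene was called in opposite directions.

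**Figure D3:**
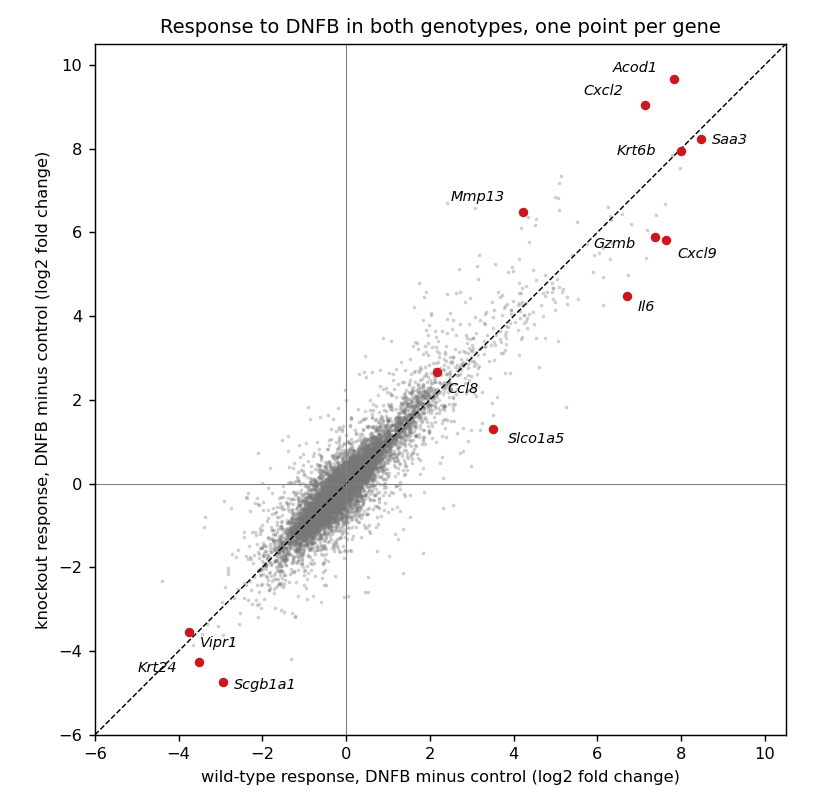
Log2 fold change, DNFB minus control, of each of 13383 genes in wild-type ears (horizontal) and in knockout ears (vertical); the dashed line marks equality. The points follow a total least squares slope of 1.07 with r = 0.906 across genes.

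Whether the genotypes respond differently was tested as the difference of the responses (knockout minus wild type). Slco1a5, an organic anion transporter, had a smaller increase in knockout ears: the difference was -2.20 ± 0.20 (n = 3 per group, adjusted p = 0.016). Its mean intensity went from 2.08 to 23.8 in wild-type and from 7.31 to 18.2 in knockout ears, so both control groups lay below 16 and the size of the difference depends on the background handling (-0.36 after adding 32). The call of Slco1a5 was lost with no filter, with trend and robust eBayes, after adding 32, with washing run or mouse as a block, and without wild-type control array 1 or 3, knockout control array 1 or 2, or knockout DNFB array 1 or 3 (adjusted p = 0.0046 to 0.57 over its alternatives). Among the genes with the next smallest p, which did not pass, the epidermal protease Klk6 differed by -1.83 ± 0.26 (adjusted p = 0.21) and Slc5a8, a transporter of short-chain fatty acids, by -1.13 ± 0.15 (adjusted p = 0.17). Pde1b differed by -1.07 ± 0.16 (adjusted p = 0.21). Ccl8 differed by 0.50 ± 0.16 (adjusted p = 0.68).

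Camera shifted 7 lists in this comparison. The cell cycle list had the larger response in knockout ears (median difference 0.48, 26 of 28 genes above 0, adjusted p = 1.8e-09), with the proliferation marker Mki67 at 0.85 ± 0.36. The epidermal differentiation list had the lower one (median -0.36, 20 of 22 genes below 0, adjusted p = 2.3e-10), with Casp14 at -0.94 ± 0.27, Alox12b at -0.88 ± 0.26 and the corneodesmosome protein Cdsn at -0.87 ± 0.20. In the latter list 8 genes were lower adjusted over the list alone. The epidermal stress list (median -0.46, adjusted p = 9.7e-04), the sebaceous list (-0.34, adjusted p = 7.8e-04) and the muscle list (-0.32, adjusted p = 0.0026) were also lower. The type 2 list (0.47, adjusted p = 0.0213) and the hair follicle list (1.20, or 0.83 at the bound, adjusted p = 0.0028) were higher, the former with Ccl24, a chemokine for eosinophils, at 2.07 ± 0.50 and Arg1 at 1.61 ± 0.55. No member passed over all genes, and adjusted over the list alone 1 gene each passed in the type 2, stress and sebaceous lists. With an estimated correlation none of the 7 remained (adjusted p = 0.387 for the cell cycle, differentiation and type 2 lists, 0.789 for the sebaceous list and 0.79 for the others). Fry gave 0 lists moving one way and 3 moving in either direction. Median, mean and test differed in sign for the B cell, eosinophil, neutrophil, endocannabinoid and immediate early lists, none of which passed.

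Per mouse, the differentiation list changed by 0.10, 0.16 and -0.03 in wild-type and by -0.22, -0.24 and -0.47 in knockout mice. The cell cycle list changed by 1.64, 1.86 and 1.56 in wild-type and by 1.94, 2.40 and 2.01 in knockout mice. These were the 2 lists whose mice did not overlap, where chance gives 3.1 of 31; the two-sided exact permutation p was 0.1, the smallest this design allows, and 0.845 after adjustment over the lists.

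**Figure D4:**
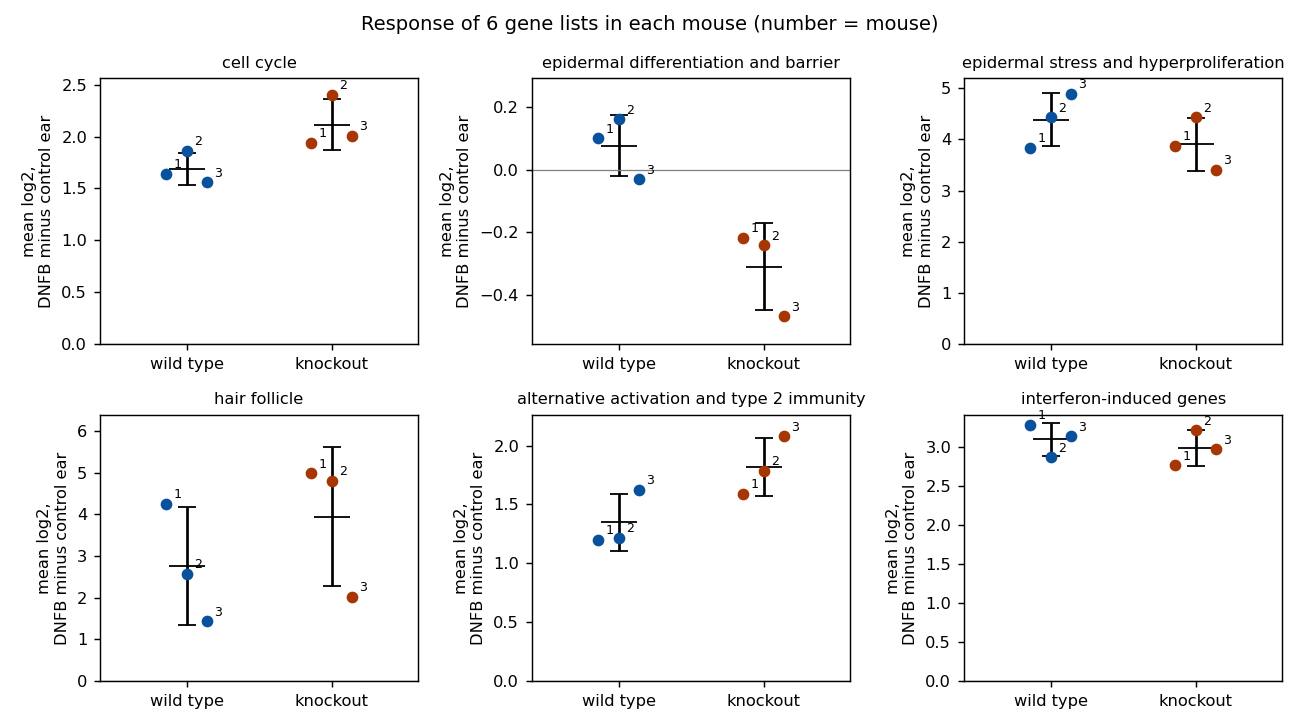
Mean log2 change, DNFB-treated minus control ear, of 6 gene lists in each of 3 wild-type and 3 knockout mice (points, numbered by mouse), with the mean and SD per genotype. The cell cycle values were 1.56 to 1.86 in wild-type and 1.94 to 2.40 in knockout mice, and the epidermal differentiation values -0.03 to 0.16 and -0.47 to -0.22.

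For single probe sets, 1833 differed at an unadjusted p under 0.05, where 1473 are expected by chance, and 1 passed the adjustment in limma; with mouse as a block 0 passed (1882 at the unadjusted p). The count was 0 without wild-type control array 1 or 3, knockout control array 1 or 2, or knockout DNFB array 1, was 2 without wild-type control array 2 or wild-type DNFB array 3, and 3 without wild-type DNFB array 1 or knockout DNFB array 2. Camera gave 11 lists without wild-type DNFB array 1 and 4 without knockout DNFB array 1. With washing run as a block the type 2 list (median 0.32 against 0.47, adjusted p = 0.054) and the hair follicle list (-0.61 against 1.20, adjusted p = 0.692) did not pass and the muscle list turned to a median of 0.33 (adjusted p = 0.0097). The other 4 kept their direction and their call at the preset correlation, the cell cycle list at a median of 0.38 (adjusted p = 1.2e-04) and the differentiation list at -0.41 (adjusted p = 3.7e-07), and the immediate early list passed downward (median -0.37, adjusted p = 0.0056). Without the block, an estimated correlation left none of these calls (adjusted p = 0.387 for cell cycle and differentiation, 0.79 for stress and 0.789 for sebaceous).

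The third comparison asks which genes differ between genotypes in DNFB-treated ears. Mmrn1, multimerin 1 of platelets and endothelium, was at least 6.38-fold higher in knockout ears (n = 3 per group, adjusted p = 0.016), with mean intensities of 4.87 in wild type and 102.0 in knockout. Cd209e, a lectin of the DC-SIGN family, was higher by 1.46 ± 0.20, Lox, the collagen cross-linking lysyl oxidase, by 0.65 ± 0.09, and the histone H2ax by 0.62 ± 0.09 (adjusted p = 0.037, 0.038 and 0.038). Zfp593 was lower by -2.27 ± 0.17 (adjusted p = 6.5e-04), Wdfy1 by -1.37 ± 0.20, Efcab7 by -1.31 ± 0.19, Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, by -1.26 ± 0.17, and Cep85 by -1.25 ± 0.18 (adjusted p = 0.037 to 0.038). Ccl8 was 3079 in wild-type and 5117 in knockout ears, a difference of 0.73 ± 0.12 that did not pass (adjusted p = 0.065; 0.0012 to 0.47 over its alternatives).

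Camera shifted 8 lists between DNFB-treated ears of the genotypes. The epidermal differentiation list was lower in knockout ears (median -0.37, 21 of 22 genes below 0, adjusted p = 2.4e-12; 16 genes lower adjusted over the list alone), with the barrier proteins Hrnr at -0.60 ± 0.16 and Flg at -0.59 ± 0.22. The epidermal stress list (median -0.29, adjusted p = 0.0032) and the muscle list (-0.24, adjusted p = 7.5e-05) were also lower, in all 21 genes of each. The extracellular matrix list was higher (median 0.34, 17 of 20 genes, adjusted p = 1.15e-05), with Lox past the threshold, 8 genes adjusted over the list alone, Timp1 at 0.74 ± 0.25 and Mmp9 at 0.74 ± 0.26. The cell cycle list (median 0.23, 26 of 28 genes, adjusted p = 1.1e-05, with the kinase Plk1 at 0.53 ± 0.18), the type 2 list (0.24, 9 of 11 genes, adjusted p = 0.0064), complement (0.30, 8 of 11 genes, adjusted p = 0.0474) and hair follicle (0.74, all 19 genes, adjusted p = 0.0474) were higher. In the type 2 list Ccl24 differed by 1.85 ± 0.35 (adjusted p = 0.15) and Arg1 by 1.32 ± 0.39 (adjusted p = 0.36), with 2 genes past the threshold adjusted over the list alone. None of the 8 lists remained with an estimated correlation (adjusted p = 0.267 for differentiation and type 2, 0.314 for matrix, 0.646 for cell cycle, muscle, stress and complement, and 0.651 for hair follicle). Fry gave adjusted p = 0.0326 for differentiation, 0.0326 for type 2 and 0.0378 for matrix. Median, mean and test differed in sign for the T and NK cell, interferon, endocannabinoid, immediate early and nerve lists, none of which passed.

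In all, 17 probe sets were higher and 18 lower in knockout than in wild-type DNFB-treated ears (4 and 5 genes), with 2767 at an unadjusted p under 0.05. The total was 17, 22 and 13 without wild-type array 1, 2 or 3, and 12 and 19 without knockout array 2 or 3. Without knockout array 1 it was 34, with 7 higher and 27 lower; without knockout array 2 or 3, 4 and 5 were higher. Of the genes named, Zfp593 kept its call without each of the 6 arrays, and the other 8 lost theirs without at least 3 of them. No washing run held DNFB-treated ears of both genotypes; with the run as a block, which links them only through the control ears, 3 probe sets passed, and 4 of the 8 lists did not. The median of the cell cycle list went from 0.23 to 0.12 (adjusted p = 0.106), of muscle from -0.25 to -0.05 (adjusted p = 0.21) and of complement from 0.30 to 0.16 (adjusted p = 0.601), while that of hair follicle stayed at 0.78 against 0.74 (adjusted p = 0.0655). The lists that passed only with this block were MHC class II, monocyte and macrophage, eosinophil and melanocyte (higher) and sebaceous, adipocyte and immediate early (lower, the last with a median of -0.75 and adjusted p = 3.9e-06), 11 lists in all, and the median of the stress list went from -0.29 to -1.25. Without wild-type array 2, and without knockout array 1, 6 of the 8 lists remained, and without wild-type array 3 or knockout array 2 or 3, 7 did.

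The fourth comparison asks which genes differ between genotypes without DNFB. In control ears Mmrn1 was at least 13.1-fold higher in the knockout (adjusted p = 0.0032, n = 3 per group), at 6.16 in wild type and 209.8 in knockout. Hacl1, an enzyme of fatty acid alpha-oxidation, was higher by 1.79 ± 0.22, Cyp1a1, a target of the aryl hydrocarbon receptor, by 1.79 ± 0.25, and Degs2, a sphingolipid hydroxylase, by 1.76 ± 0.21. The lipid droplet gene Hilpda (1.61 ± 0.23), Klk6 (1.52 ± 0.19), Lhpp (1.31 ± 0.18) and Pde1b (1.05 ± 0.11) were higher too, and Ly6i was higher at least 1.22-fold. Slco1a5 passed, but both groups lay below 16, so no size is given. Lower in the knockout were Zfp593 (-2.07 ± 0.17), Paqr7, a membrane progesterone receptor (-2.02 ± 0.26, from 1161 to 286), Nnt (-1.71 ± 0.17), Efcab7 (-1.30 ± 0.19), Wdfy1 (-1.28 ± 0.20), Alg6 (at least 2.36-fold), Akr1c18, a progesterone-metabolizing enzyme (-1.21 ± 0.10), Kdf1 (-1.13 ± 0.18) and Trnp1 (-0.82 ± 0.12). These genes had adjusted p = 9.0e-04 to 0.049. None of the 31 lists was shifted by camera. The smallest adjusted p was 0.0543, for the cell cycle list (median -0.20) and the sebaceous list (median 0.18). Fry in either direction gave 5 lists. Without single arrays 1 to 3 lists passed: 2 each without wild-type control array 1 or 2 or knockout control array 1, 3 without knockout control array 2 and 1 without knockout control array 3. With washing run as a block 11 lists passed, among them interferon (median 0.49, adjusted p = 3.2e-05), muscle (-0.39, adjusted p = 5.8e-05), stress (-0.61, adjusted p = 3.6e-04) and melanocyte (0.72, adjusted p = 0.0016).

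In control ears 24 probe sets were higher and 20 lower in the knockout (11 and 9 genes), with 3467 at an unadjusted p under 0.05. The total was 206 (48 higher and 158 lower) without knockout control array 1 and 25 without knockout control array 2. Knockout control array 1 had the lowest array weight of the 12 (0.606). It correlated at r = 0.965 with wild-type control arrays 1 and 2, at 0.9616 with wild-type control array 3, and at 0.9618 and 0.9621 with the other arrays of its own group. No run held control ears of both genotypes, and with the run as a block 4 probe sets passed. The Actb ratio was lower in knockout than in wild-type control ears, at 0.48 against 0.66, while that of Gapdh was -0.38 against -0.40.

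The knocked-out genes themselves were near the lower limit of the arrays. Cnr1 had mean intensities of 9.85, 11.6, 11.0 and 8.23 in wild-type control, wild-type DNFB, knockout control and knockout DNFB ears on one probe set and 12.8, 8.20, 9.95 and 7.86 on another. Cnr2, the receptor of immune cells, had 12.0, 23.2, 12.9 and 32.4. The DNFB response of Cnr2 did not pass in wild-type ears (adjusted p = 0.072) and was at least 2.02-fold in knockout ears (adjusted p = 0.018, a call lost with run or mouse as a block and without knockout control array 2 or 3 or knockout DNFB array 2). Neither gene passed in a genotype comparison (adjusted p = 0.72 to 0.95). Which part of each gene the probes cover relative to the deletion is not given, so these levels do not check the genotype.

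Cnr1 and Cnr2 both lie on chromosome 4, and knockout alleles can carry neighbouring sequence of another strain, so genotype calls near them were counted. In the mean of both ears, 33 probe sets were higher and 43 lower in the knockout (28 genes). Of the 100 tested genes nearest to Cnr2, 7 were called, against 21 of 13232 others (odds ratio 47.2, two-sided Fisher's exact p = 1.1e-09): Zfp593, Paqr7, Cep85, Kdf1, Trnp1, Pithd1 and Pnrc2, all lower in the knockout, by -0.65 to -2.17. In control ears 4 of the 100 were called (odds ratio 34.4, exact p = 1.3e-05) and in DNFB-treated ears 2 (odds ratio 38.5, exact p = 0.0019). Near Cnr1 0 of 100 were called in either kind of ear or in their mean by limma. On the whole chromosome 11 of 804 genes were called in the mean of both ears (odds ratio 10.2, exact p = 3.0e-07).

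**Figure D5:**
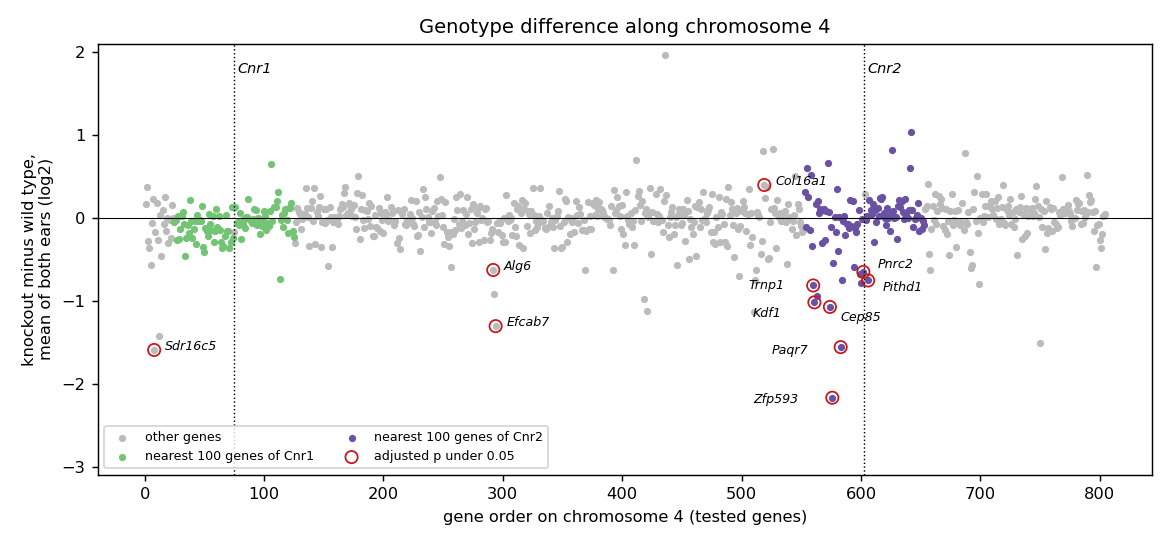
Knockout minus wild-type log2 difference, mean of both ears, of each of 804 tested genes in gene order along chromosome 4; purple and green points are the 100 genes nearest to Cnr2 and Cnr1, and circles mark genes with an adjusted p under 0.05. Among the genes nearest to Cnr2, 7 are circled, all below 0, and none near Cnr1.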

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

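The tests of each list with the washing run as a block were chosen only after the results were seen. A difference between the genotypes' DNFB responses, tested as an interaction, singled out 1 gene and 7 lists. For Slco1a5 the knockout response was lower by -2.20 on the log2 scale, with control levels below an intensity of 16. The median differences of the lists were 0.48 for cell cycle, -0.36 for epidermal differentiation and barrier, -0.46 for epidermal stress and hyperproliferation, 0.47 for alternative activation and type 2 immunity, 1.20 for hair follicle, -0.34 for sebaceous gland and lipid synthesis and -0.32 for skeletal muscle markers. With an estimated correlation 0 of these 7 lists passed in camera. With the washing run as a block the median of the hair follicle list turned to -0.61 and that of the muscle list to 0.33. Of the 10 splits of the samples, 2 gave as many probe sets as the real 1, and the highest other gave 3; 10 splits are too few for a share under 0.05.

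The cell cycle list had the larger increase in knockout ears and the epidermal differentiation list the lower response. Each had adjusted p = 0.387 in camera at an estimated correlation. These were the 2 lists whose mice did not overlap, where chance gives 3.1 (adjusted permutation p = 0.845). Between genotypes the cell cycle median was 0.23 in DNFB-treated and -0.20 in control ears, where the list did not pass. The larger increase thus came in part from lower levels in knockout control ears. With the washing run of the arrays as a block, the differentiation list kept 1.15 times its median difference (-0.41). Its mean went from -0.39 ± 0.11 to -0.40 ± 0.17. That blocked value rests on 1 wild-type DNFB and 1 knockout control array, so the run as the cause stays open for that list. The cell cycle list kept 0.799 of its median (0.38, camera adjusted p = 1.2e-04), but its mean went from 0.43 ± 0.15 to 0.37 ± 0.24, an error too wide to exclude that most of the difference came with the run, which stays open for that list. A lower share of epidermis in the DNFB-treated knockout ears was tested on 21 keratinocyte genes outside the list. Their mean difference was -0.03 ± 0.08 (-0.0292, 12 of 21 lower), against -0.34 ± 0.10 for the list. A fall as large as the list's lies outside the error of these genes. That error is too wide to exclude a smaller fall, set in advance as enough, which keeps this explanation open. A biological candidate explanation, more proliferation and less differentiation of keratinocytes without the receptors, stays untested. The differentiation list also holds the basal keratins Krt5, Krt14 and Krt15, so its shift does not separate differentiated from basal keratinocytes. The cell cycle list is not made of keratinocyte genes, so in whole ears its change cannot be assigned to these cells.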

How the results depend on the processing

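Washing run as a random block, and the normalization and run alternatives of the lists, were chosen only after the results were seen. With the run as a fixed block the probe sets past the threshold were 5624 in the wild-type and 5791 in the knockout response (5346 and 5507 shared with the reported ones), 3 and 4 between genotypes in DNFB-treated and control ears and 2 for the difference of the responses (1, 1 and 0 shared with the reported ones); a block leaves fewer residual degrees of freedom, and no run holds one ear type of both genotypes. Inside a run, the wild-type response compares 1 DNFB array with the controls, and the knockout response 1 control array with the DNFB arrays. Values with the fixed block thus rest on single arrays. With the run as a random block the counts were 58 and 128 between genotypes in DNFB-treated and control ears, and 3 for the difference of the responses. Calls of at least 2-fold numbered 3571 and 3940 in the responses, by construction. Between genotypes in DNFB-treated ears there were 13 with no filter, 92 with trend and robust eBayes, 66 after adding 32 and 7 with only the groups compared. In control ears there were 79 with the stricter filter, 127 with trend and robust eBayes, 116 after adding 32, 85 with array weights and 14 with only the groups compared. For the difference of the responses there were 0 with no filter, 0 with the stricter filter, 0 with mouse as a block, 4 with trend and robust eBayes and 3 after adding 32, none of them the reported Slco1a5. Leaving out single arrays gave 9011 to 9502, 9739 to 10551, 12 to 34, 25 to 206 and 0 to 3 in the 5 comparisons. Of the lists, an estimated correlation left 6 in each response and 0 in DNFB-treated ears and in the difference. Fry gave 28 (mixed) in the wild-type response, 3 (directional) in DNFB-treated ears, 5 (mixed) in control ears and 0 (directional) and 3 (mixed) for the difference. In control ears, where 0 lists passed, there were 1 with the stricter filter, 11 with the run as a block, 2 with centred arrays and 3 after adding 32. Leaving out single arrays gave 18 to 19 lists in each response, 6 to 11 in DNFB-treated ears, 0 to 3 in control ears and 4 to 11 for the difference. With mouse as a block the eosinophil list passed camera in wild-type (adjusted p = 0.0281) and knockout ears (adjusted p = 0.0379). The extracellular matrix list then passed in the difference (adjusted p = 0.0485). The skeletal muscle list reversed in the difference with the run as a block (adjusted p = 0.00972). The responses of both genotypes correlated at 0.957 and 0.953 over genes called in the wild type and knockout (slopes 1.02 and 1.11) and at 0.946 after adding 32; leaving out single arrays gave 0.886 to 0.902, with slopes of 1.05 to 1.12. With list medians 4 lists separated the mice, and among the 20 genes nearest to Cnr2 0 were called by limma in control and 0 in DNFB-treated ears, but 2 in the mean of both ears (odds ratio 56.6, exact p = 7.9e-04). Except where stated, the cause was not tested. Intensities below 16 limit fold changes to lower bounds.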

Other observations

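The 10 lists in this part, the probe set test of Mmrn1 and the washing run tests of Mmrn1 and Nnt were chosen only after the results were seen, and the Fisher test near Cnr2, itself planned, was taken as a test of kept strain sequence only then. Of 18 circadian clock genes, 13 fell and 2 rose in wild-type ears (median -1.02, adjusted p = 1.4e-04 by camera and 0.025 with an estimated correlation), with a median of -1.20 in knockout ears. The repressor Per2 changed by -2.12 ± 0.23, the output factor Hlf by -2.08 ± 0.17 and Nr1d1 by -1.93 ± 0.11, while Nfil3 rose by 1.27 ± 0.20. Of 12 inflammasome genes, 11 rose in wild-type and 10 in knockout ears (medians 1.48 and 1.90; adjusted p = 0.0039 and 0.0063 with an estimated correlation), among them the inflammatory caspases Casp4 (3.00 ± 0.18) and Casp1 (1.85 ± 0.13). Of 15 regulatory receptors and signal inhibitors 10 rose in wild-type ears (median 1.13; adjusted p = 0.049 with an estimated correlation, and 0.054 in knockout ears), with the checkpoint ligand Cd274 at 2.09 ± 0.15.

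Of 13 kallikreins and their inhibitors, 10 rose in wild-type ears. The desquamation protease Klk13 rose by 6.30 ± 0.23 and Klk6 by 4.62 ± 0.19, against 5.36 ± 0.23 and 2.78 ± 0.19 in knockout ears. The median difference of the responses was -0.60 (camera adjusted p = 2.9e-10, and 0.144 with an estimated correlation). This p is no independent support, since Klk6 was already among the genes with the smallest p in that comparison. As for all lists in this part, it is adjusted over the 10 added lists only. Knockout minus wild type, the kallikrein median was 0.26 in control and -0.33 in DNFB-treated ears (camera adjusted p = 0.033 and 1.9e-07). The smaller knockout response thus includes a higher control level. Respiratory chain genes were also higher in knockout control ears (median 0.09, camera adjusted p = 0.0031). With an estimated correlation neither list passed between genotypes. In wild-type ears glycolysis genes rose in 9 of 17 cases (median 0.82), with Pgam1 at 1.51 ± 0.11 and Ldha at 1.22 ± 0.13. The medians in wild-type ears were 0.53 for 16 unfolded protein response genes, 0.77 for 10 metallothionein and acute phase genes, 0.18 for 22 respiratory chain genes, 0.33 for 17 NRF2 targets and 0.01 for 18 eicosanoid genes, with adjusted p = 0.0036, 0.0046, 0.0012, 0.0132 and 0.563 by camera. With an estimated correlation none of these 7 lists passed in wild-type ears.

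Of the 11 genes on chromosome 4 called in the mean of both ears, 7 were among the 100 nearest to Cnr2, and Alg6, Col16a1, Efcab7 and Sdr16c5 lay elsewhere. Washing run as a block left the median difference of the 7 neighbour genes at 1.11 times its size, -1.02 without and -1.13 with it. In the 1 run that holds both genotypes, knockout control and wild-type DNFB ears differ in treatment too. The blocked value thus also rests on the responses of 1 wild-type DNFB and 1 knockout control array, so the run as the cause stays open. Sequence of the embryonic stem cell strain kept around the gene is a candidate explanation, with an odds ratio of 47.2. Of the 6 neighbour genes with another tested probe set, 2 (Paqr7 and Pnrc2) moved the same way on one, Pnrc2 at -0.28 ± 0.10 but at 0.39 ± 0.24 on yet another, so strain variants under single probe sets may account for part of the others. No effect of the receptors themselves on these genes was tested.

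Mmrn1 was near the floor in wild-type and Nnt low in knockout ears. With the run as a block 0.738 of the Nnt difference remained (-1.49 ± 0.12 without and -1.10 ± 0.27 with it). That blocked value rests in part on 1 wild-type DNFB and 1 knockout control array, so the run stays open for Nnt. Inside the run that holds both genotypes Mmrn1 was at least 11.6-fold higher in the 2 knockout control than in the 2 wild-type DNFB arrays. This ratio lies above the largest between ears of one genotype (3.02), which argues against the run as the whole cause for Mmrn1. Another probe set of Nnt also fell (1 of 1, -2.13 ± 0.15), against a single faulty probe set; Mmrn1 has 0 other tested probe sets, so this stays open for it. Different C57BL/6 substrains of the lines are a candidate explanation, since some carry a deletion in Nnt and others one that includes Mmrn1. However, 0 probe sets of the neighbouring gene named in advance were tested. The ears with the higher Nnt and with Mmrn1 near the floor were the wild-type ones, labelled C57BL/6J. Their Nnt was 224.5 in control and 158.7 in DNFB ears, against 68.8 and 66.1 in knockout ears. Whether the wild-type mice were of the substrain that the label names was not tested. A difference of substrain could not be told apart from receptor loss in any comparison of the genotypes or of their responses.

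With 10 splits of the samples per comparison, no share under 0.05 can be reached. The real split gave 11211 probe sets in the wild-type response and the highest other 0, and in the knockout response 11501 and 1. Every other split of a response mixes DNFB and control ears in both sets, which puts the response into the residual spread. Few calls in those splits were thus fixed in advance, and the contrast says nothing about chance. Between genotypes the real splits gave 35 in DNFB-treated ears, with 24 for the highest other, and 44 in control ears, with 1. In each of these 4 comparisons 1 split, the real one, gave as many.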
